A study of Mus musculus with 9 samples.

How the data were processed

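The samples are livers of male C57BL/6J mice, 3 on chow with vehicle, 3 on CDAA-HFD with vehicle and 3 on CDAA-HFD with 326E at 30 mg/kg for 6 weeks, each sequenced as 1 poly(A) RNA library. The titles of all libraries, chow included, begin with MCD, which often stands for another diet, deficient in methionine and choline, while the protocol in the labels says that these mice received CDAA-HFD or normal chow, and the protocol is followed here. Per the labels, reads were aligned with HISAT2 and counted with featureCounts on mm10. Versions, the annotation release and the strand setting are not stated, so overlapping and antisense genes are uncertain. The deposited values are FPKM for 54532 genes in 9 libraries, with a gene length. Multiplied by length, the deposited FPKM gave whole reads to within 0.01 in 100% of values, so assigned reads per library could be read back, 13275888 to 17058316. The library sizes in the deposited FPKM are not these totals. They equal median-of-ratios sizes, at 0.83 to 1.19 of the totals, so the values were already scaled between libraries. One read in a gene of 2 kb is 0.0246 to 0.0455 FPKM, and the number of reads limits the precision of low values. Reads of replicates differed by far more than counting error, with chi-square per degree of freedom from 20.5 to 79.5. Of the 54409 genes that are also in GENCODE vM21, 98.3% have the same coordinates there.

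Genes with at least 0.5 FPKM in at least 3 of the 9 libraries, 13737 of them, were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM+1), with a variance trend, all 9 libraries in 1 fit and 6 residual degrees of freedom. The comparisons were vehicle against chow, 326E against vehicle and 326E against chow. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene was called at an adjusted p under 0.05. The 31 gene lists, with 772 members, were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. The lists cover lipid, bile acid, methyl donor, glucose, respiratory, xenobiotic, stress, cell cycle and clock genes, matrix, inflammation, and markers of liver cell types and of carried-over tissue, and 3 genes are in more than 1 list. Because the diet and 326E comparisons share the vehicle libraries, their overlap and covariance were set against 100 simulated data sets. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

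Named genes followed a rule: in the diet and 326E comparisons, the 5 called protein-coding genes with the largest rise and the 5 with the largest fall, without overlap between groups and with a group mean of at least 1 FPKM; the 2 called members of each list with the largest change; and Acly, Ppara, Cyp4a10, Cyp4a14, Acot1, Pdk4, Fgf21, Fasn, Scd1, Sqle, Col1a1, Acta2, Timp1, Trem2 and Ccl2 whatever their values. For opposite calls it took the 5 largest in each direction. The comparisons, tests, lists, this rule and most alternatives were chosen before the data were examined. Results of some single genes are not reported here. Other genes are said to be chosen afterwards where they are named.

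The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 1, median-of-ratios scaling, quantile normalization, no variance trend, array weights, only the libraries of each comparison, voom on the whole reads, a length trend removed, protein-coding genes only, a replicate block, and each library left out in turn. Values scaled to total assigned reads, a GC trend removed, the Mup family left out and only vehicle replicate 2 kept were added after the values were seen. The method was tested on simulated data with 3 libraries per group: of genes changed 2-fold, 65.2% were recovered for 326E, and 3.7% of calls were of unchanged genes, against 8.1% for the diet. The shares of false calls rest on 134 calls for 326E and 136 for the diet. Far fewer genes changed there than were called in the real data, and genes varied independently, so these shares need not hold for the real data. No library was left out of the reported values.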

Results

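Liver messenger RNA was measured in 9 libraries from male C57BL/6J mice in 3 groups of 3. One group received chow and vehicle. The other groups received a choline-deficient, L-amino acid-defined, high-fat diet (CDAA-HFD), which produces steatohepatitis and fibrosis in mice, with vehicle or with 30 mg/kg of the compound 326E for 6 weeks. The title of the series names ATP citrate lyase (ACLY) and PPARα as targets of 326E. Between 13275888 and 17058316 reads per library were assigned to genes, and 13737 of 54532 genes were tested. Values are mean FPKM ± SD of 3 libraries per group, and log2 fold changes are differences of log2(FPKM+1), with their standard error after ±. The labels speak of mice but do not say that each library is a separate animal. The p-values of single genes therefore measure the spread between these samples. The list p-values from camera at its preset correlation rest instead on the spread across genes, taken as nearly independent. The estimated correlations ranged from -0.105 (B and plasma cells) to 0.633 (acute phase), with 0.437 for macrophage and 0.488 for collagen genes. Small list p-values at the preset correlation are therefore not evidence at the level of samples. On mm10, 5 of the named genes are Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), Scd1 (ENSMUSG00000037071, chromosome 19, 44394451 to 44407709), Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142), Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000) and Ppara (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819).

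The 3 groups separated. Spearman correlations across genes were 0.957 to 0.975 within groups, 0.865 to 0.885 between chow and vehicle libraries, 0.926 to 0.949 between vehicle and 326E libraries, and 0.907 to 0.934 between chow and 326E libraries. On the first principal component, 56.2% of the variance, the 326E libraries (3.53 to 12.03) lay between chow (-52.89 to -45.32) and vehicle (36.83 to 41.31). On the second, 15.3% of the variance, vehicle replicates 1 and 3 stood at 21.84 and 21.99 and vehicle replicate 2 at 5.28. Immediate early genes, which cells switch on within minutes of a stimulus, followed the same separation: their median against chow was 2.64, 1.17 and 3.43 in vehicle replicates 1, 2 and 3, and 0.8, 0.7 and 0.49 in the 326E libraries. This list was written after the values were seen. Mitochondrial genes took 7.52% of the reads in chow, 5.70% in vehicle and 6.84% in 326E libraries.

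**Figure D1:**
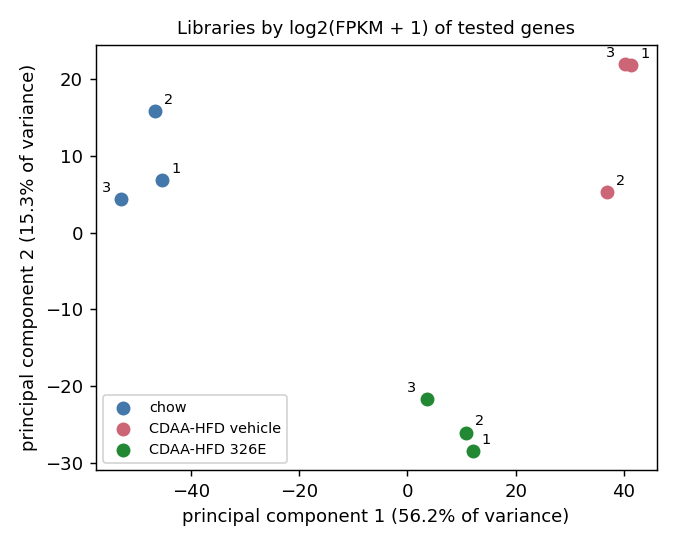
Principal components 1 and 2 of log2(FPKM+1) over the tested genes, each point a library labelled with its replicate number and coloured by group. The 326E libraries lie at 3.53 to 12.03 on component 1, between chow and vehicle, and vehicle replicate 2 lies at 5.28 on component 2.

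The first comparison asked what the CDAA-HFD changed, vehicle against chow. Macrophage, matrix and inflammatory lists rose, and lists of fatty acid synthesis and oxidation, bile acid and hepatocyte function genes fell. None of these lists passed with an estimated correlation (adjusted p = 0.0564 to 0.451), and quantile normalization ended the calls of fatty acid synthesis, oxidation and hepatocyte function. Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 0.0424 ± 0.0167 FPKM in chow and 134 ± 23 FPKM in vehicle livers. Col1a1, a chain of type I collagen, rose from 1.11 ± 0.655 to 33.4 ± 10.7 FPKM, and Scd1, the desaturase that makes monounsaturated fatty acids, fell from 1623 ± 634 to 20 ± 6.73 FPKM. Of the tested genes, 5721 passed, 2859 higher and 2862 lower, and 1059 and 488 of them changed at least 2-fold on the log2(FPKM+1) scale. Of the called genes 50% were higher, and 84.3% with values scaled to total assigned reads, a scaling that moved the median of all genes from -0.04 to 0.25. The medians of the cholesterol, Kupffer cell, peroxisomal and unfolded protein lists then turned from -0.15, -0.18, -0.33 and -0.09 to 0.15, 0.17, 0.07 and 0.25. Camera, which compares a list with the other genes, still pointed down for the cholesterol, peroxisomal and unfolded protein lists, and turned from up to down for the Kupffer cell list, which did not pass either way (adjusted p = 0.846 and 0.989). With only vehicle replicate 2 kept, 3456 genes passed, the lone library being assumed to vary like the other groups.

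Genes of recruited and lipid-associated macrophages rose together: of 29 tested, 28 rose, 0 fell and 1 did not pass (28 and 0 adjusted over the list alone). Their median was 1.84, with adjusted p = 4.7e-18 and adjusted p = 0.175 with an estimated correlation. Trem2, a lipid receptor of these cells, rose by 3.47 ± 0.28, and Lgals3, a galectin, by 4.68 ± 0.41. Among chemokines, cytokines and inflammasome genes, of 27 tested, 25 rose, 0 fell and 2 did not pass (27 and 0 adjusted over the list alone). Their median was 1.62, with adjusted p = 5.34e-13 and adjusted p = 0.0564 with an estimated correlation. Ccl2, which attracts monocytes, rose by 3.64 ± 0.41. Dendritic cell and antigen presentation genes gave a like result: of 14 tested, 13 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone). Their median was 1.43, with adjusted p = 2.84e-07 and adjusted p = 0.175 with an estimated correlation. The class II gene H2-Eb1 rose by 2.63 ± 0.27. For interferon-stimulated genes, of 25 tested, 16 rose, 2 fell and 7 did not pass (16 and 2 adjusted over the list alone). Their median was 0.91, with adjusted p = 7.42e-05 and adjusted p = 0.357 with an estimated correlation. Neutrophil markers also rose: of 8 tested, 6 rose, 0 fell and 2 did not pass (7 and 0 adjusted over the list alone). Their median was 1.32, with adjusted p = 0.00605 and adjusted p = 0.408 with an estimated correlation, and this call was lost when scaled to total assigned reads (adjusted p = 0.0516) and with only vehicle replicate 2 kept (adjusted p = 0.0575). Kupffer cell markers went both ways: of 15 tested, 6 rose, 3 fell and 6 did not pass (6 and 3 adjusted over the list alone). Their median was -0.18, with adjusted p = 0.846 and adjusted p = 0.917 with an estimated correlation, where the mean was 0.06 and the test pointed up. Timd4, a receptor of resident macrophages, fell by 1.51 ± 0.26. T and NK cell genes (median 0.51, 3 up and 0 down of 9, adjusted p = 0.0621 and adjusted p = 0.451 with an estimated correlation) and B and plasma cell genes (median 0.13, 2 up and 0 down of 9, adjusted p = 0.301 and adjusted p = 0.451 with an estimated correlation), whose median turned to -0.002 with quantile normalization, did not pass as lists. The T and NK cell list passed, among other settings, without vehicle replicate 3 (0.48, adjusted p = 0.033), without 326E replicate 3 (0.51, adjusted p = 0.0201) and with only vehicle replicate 2 kept (0.74, adjusted p = 0.028).

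Matrix genes rose. For collagens and matrix proteins, of 29 tested, 26 rose, 1 fell and 2 did not pass (27 and 1 adjusted over the list alone). Their median was 1.46, with adjusted p = 2.07e-12 and adjusted p = 0.25 with an estimated correlation. Lum, a proteoglycan that orders collagen fibrils, rose by 3.01 ± 0.23. For matrix remodelling genes, of 26 tested, 23 rose, 0 fell and 3 did not pass (24 and 1 adjusted over the list alone). Their median was 1.61, with adjusted p = 5.53e-11 and adjusted p = 0.175 with an estimated correlation. Mmp12, a macrophage elastase, and Timp1, a metalloproteinase inhibitor, rose by 6.28 ± 0.20 and 3.11 ± 0.21. For stellate cells and myofibroblasts, of 24 tested, 16 rose, 0 fell and 8 did not pass (18 and 0 adjusted over the list alone). Their median was 0.95, with adjusted p = 8.09e-07 and adjusted p = 0.296 with an estimated correlation. Acta2, the smooth muscle actin of myofibroblasts, had a value of 1.59 ± 0.58 (adjusted p = 0.055), which passed without chow replicate 1 (2.19, adjusted p = 0.0108) or vehicle replicate 1 (2.12, adjusted p = 0.0181). For cholangiocyte and ductular genes, of 16 tested, 9 rose, 0 fell and 7 did not pass (11 and 0 adjusted over the list alone). Their median was 1.29, with adjusted p = 0.00209 and adjusted p = 0.34 with an estimated correlation. Endothelial markers did not pass as a list (median 0.26, 6 up and 3 down of 19, adjusted p = 0.12 and adjusted p = 0.515 with an estimated correlation), except when scaled to total assigned reads (0.54, adjusted p = 0.0336). Cell cycle genes rose: of 27 tested, 23 rose, 0 fell and 4 did not pass (24 and 0 adjusted over the list alone). Their median was 0.76, with adjusted p = 3.96e-10 and adjusted p = 0.0564 with an estimated correlation. Cdkn1a, an inhibitor of cyclin-dependent kinases, was among them at 3.11 ± 0.26.

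For fatty acid and triglyceride synthesis, of 28 tested, 5 rose, 16 fell and 7 did not pass (5 and 18 adjusted over the list alone). Their median was -0.71, with adjusted p = 0.00311 and adjusted p = 0.175 with an estimated correlation. Acly fell from 43.7 ± 2.63 to 20.8 ± 4.36 FPKM (log2 -1.06 ± 0.14, adjusted p = 0.00035). For mitochondrial fatty acid oxidation, of 22 tested, 1 rose, 11 fell and 10 did not pass (2 and 11 adjusted over the list alone). Their median was -0.43, with adjusted p = 0.00455 and adjusted p = 0.451 with an estimated correlation. For peroxisomal oxidation and biogenesis, of 29 tested, 2 rose, 13 fell and 14 did not pass (3 and 14 adjusted over the list alone). Their median was -0.33, with adjusted p = 0.00455 and adjusted p = 0.451 with an estimated correlation. Scaled to total assigned reads this median turned to 0.07, below that of all genes, and the list still passed as lower (adjusted p = 0.00395). Nudt7, a peroxisomal coenzyme A hydrolase, fell by 2.49 ± 0.15. PPARα targets outside beta-oxidation went both ways (median 0.34, 13 up and 7 down of 32, adjusted p = 0.248 and adjusted p = 0.717 with an estimated correlation), with Pdk4, an inhibitor of pyruvate oxidation, at 4.23 ± 0.42 and Ppara itself at -0.40 ± 0.24 (adjusted p = 0.227). For bile acid synthesis and transport, of 23 tested, 1 rose, 17 fell and 5 did not pass (2 and 18 adjusted over the list alone). Their median was -0.92, with adjusted p = 2.96e-05 and adjusted p = 0.236 with an estimated correlation. Cyp7b1, of the alternative bile acid pathway, fell by 3.41 ± 0.34. For methyl donor and choline genes, of 26 tested, 5 rose, 15 fell and 6 did not pass (5 and 15 adjusted over the list alone). Their median was -0.67, with adjusted p = 0.00706 and adjusted p = 0.408 with an estimated correlation. Gnmt, which consumes S-adenosylmethionine, fell by 2.08 ± 0.22. Quantile normalization ended the calls of fatty acid synthesis (-0.48, adjusted p = 0.0866), mitochondrial oxidation (-0.08, adjusted p = 0.569), peroxisomal oxidation (-0.22, adjusted p = 0.448) and methyl donor genes (-0.25, adjusted p = 0.204), and brought the PPARα targets past the threshold (0.42, adjusted p = 0.00771).

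Cholesterol synthesis and uptake did not pass as a list (median -0.15, 1 up and 6 down of 25, adjusted p = 0.0959 and adjusted p = 0.716 with an estimated correlation). Its median was -0.70 in vehicle replicate 2 and -0.07 and 0.08 in replicates 1 and 3, and the list passed without vehicle replicate 1 (-0.19, adjusted p = 0.0386), without vehicle replicate 3 (-0.29, adjusted p = 0.0181), with no filter (-0.15, adjusted p = 0.00857) and with only replicate 2 kept (-0.70, adjusted p = 1.33e-05). Scaled to total assigned reads its median turned to 0.15, and the list passed as lower than the other genes (adjusted p = 0.0226). Tm7sf2, a sterol reductase, fell by 1.61 ± 0.09. Lipid droplet and VLDL genes went both ways (median 0.16, 8 up and 5 down of 20, adjusted p = 0.212 and adjusted p = 0.408 with an estimated correlation), and passed with quantile normalization (0.58, adjusted p = 0.00951).

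Hepatocyte secreted and function genes fell: of 30 tested, 0 rose, 19 fell and 11 did not pass (1 and 20 adjusted over the list alone). Their median was -0.81, with adjusted p = 2.9e-06 and adjusted p = 0.296 with an estimated correlation, and quantile normalization ended this call (-0.08, adjusted p = 0.639). Mup3, a urinary protein with close paralogs whose reads cannot be assigned with certainty, fell by 3.08 ± 0.23. For acute phase and complement genes, of 29 tested, 2 rose, 13 fell and 14 did not pass (2 and 13 adjusted over the list alone). Their median was -0.80, with adjusted p = 0.00364 and adjusted p = 0.548 with an estimated correlation, a call lost without chow replicate 2 (-0.48, adjusted p = 0.154) and with quantile normalization (-0.22, adjusted p = 0.501). For nuclear subunits of oxidative phosphorylation, of 32 tested, 0 rose, 25 fell and 7 did not pass (0 and 30 adjusted over the list alone). Their median was -0.55, with adjusted p = 4.18e-08 and adjusted p = 0.296 with an estimated correlation. Xenobiotic metabolism did not pass (median -0.46, 4 up and 9 down of 21, adjusted p = 0.0682 and adjusted p = 0.495 with an estimated correlation), and passed, among other settings, without vehicle replicate 3 (-0.62, adjusted p = 0.0391) and without 326E replicate 1 (-0.46, adjusted p = 0.0487). Ces2a, a carboxylesterase, fell by 3.63 ± 0.17. The antioxidant NRF2 list (median 0.40, 9 up and 5 down of 22, adjusted p = 0.107 and adjusted p = 0.408 with an estimated correlation) passed without vehicle replicate 2 (0.42, adjusted p = 0.0438) and with quantile normalization (0.66, adjusted p = 0.000552). Hmox1, which degrades heme, rose by 2.41 ± 0.17. The unfolded protein and integrated stress list did not pass (median -0.09, 4 up and 6 down of 24, adjusted p = 0.823 and adjusted p = 0.881 with an estimated correlation), with a mean of 0.23 against its negative median, which turned to 0.10 with quantile normalization. Glycolysis and gluconeogenesis (median 0.10, 9 up and 5 down of 26, adjusted p = 0.306 and adjusted p = 0.628 with an estimated correlation), which passed with quantile normalization (0.35, adjusted p = 0.000662), and the circadian clock (median 0.17, 4 up and 4 down of 16, adjusted p = 0.711 and adjusted p = 0.817 with an estimated correlation) did not pass otherwise. Whether the carry-over list of fat, muscle, pancreas and blood genes reflects carried-over tissue was not tested. Of its 13 tested members, 0 rose, 3 fell (Adipor2, Alas2 and Car3) and 10 did not pass (0 and 3 adjusted over the list alone). Their median was -1.27, with adjusted p = 0.0103 and adjusted p = 0.236 with an estimated correlation, and this call was lost with only vehicle replicate 2 kept (-1.26, adjusted p = 0.0735) and with quantile normalization (-1.02, adjusted p = 0.0753).

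The second comparison, the main question of the design, asked what 326E changed in CDAA-HFD livers, 326E against vehicle. Lists of fatty acid oxidation and synthesis rose, and lists of macrophage, chemokine and matrix genes fell, with many members that did not pass. None of these lists passed with an estimated correlation (adjusted p = 0.144 to 0.392). Cyp4a14, a fatty acid omega-hydroxylase with close paralogs, rose from 135 ± 38.5 to 2858 ± 545 FPKM. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, rose from 178 ± 60.1 to 2224 ± 627 FPKM, and Scd1 from 20 ± 6.73 to 1779.7 ± 393 FPKM. Gpnmb fell from 134 ± 23 to 40.6 ± 22.5 FPKM. Of the tested genes 1574 passed, 681 higher and 893 lower, with 136 and 196 changed at least 2-fold on the log2(FPKM+1) scale. Of the called genes 43.3% were higher, 51.4% with quantile normalization, 50.7% without vehicle replicate 3 and 38.3% when scaled to total assigned reads. The count was 854 without vehicle replicate 3, and 959, 647 and 712 without 326E replicates 1, 2 and 3. With only vehicle replicate 2 kept, 321 genes passed, and 38 of the 58 named genes called for 326E that had a value lost their call. Of these 38, 18 had a change at least as large as with all libraries and 13 a change smaller by over 1.5 times.

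**Figure D2:**
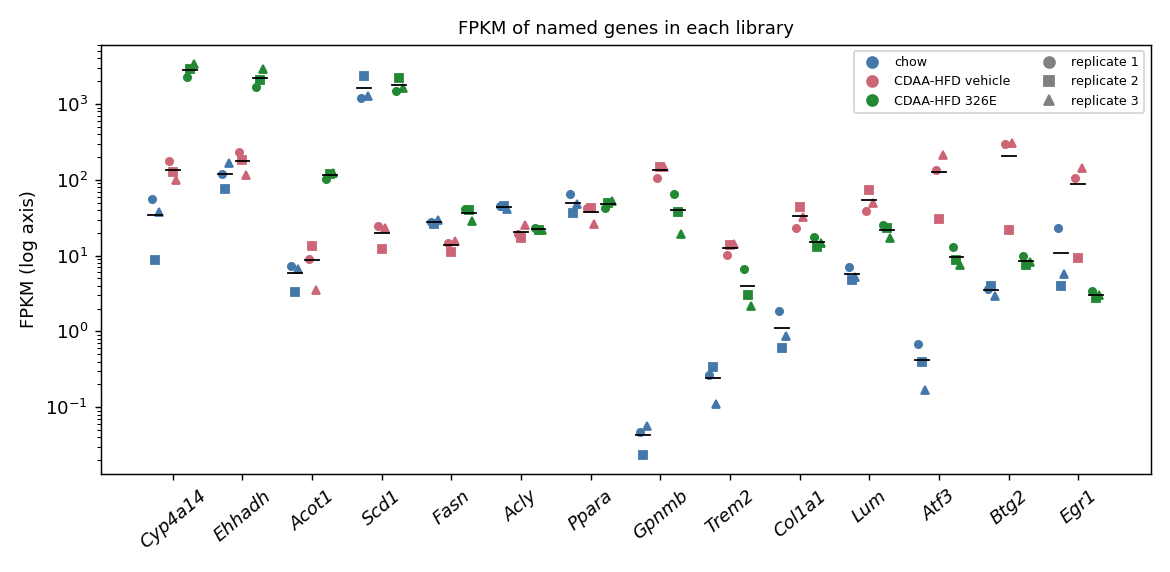
FPKM on a log axis of 14 named genes in each library, coloured by group, with a symbol for each replicate and a black line at the group mean. Cyp4a14, Ehhadh, Acot1 and Scd1 lie higher in every 326E library than in every vehicle library, and in vehicle replicate 2 Atf3, Btg2 and Egr1 lie at 30.1, 21.5 and 9.3 FPKM.

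PPARα targets outside beta-oxidation rose: of 32 tested, 21 rose, 0 fell and 11 did not pass (25 and 3 adjusted over the list alone). Their median was 1.45, with adjusted p = 9.06e-18 and adjusted p = 0.144 with an estimated correlation. Acot1, an acyl-CoA thioesterase, rose by 3.74 ± 0.40 and Cyp4a14 by 4.41 ± 0.55. Not every target moved so. Pdk4 had a value of -1.13 ± 0.42 (adjusted p = 0.118), which passed as a fall without 326E replicate 2 (-1.58, adjusted p = 0.0486), and Fgf21, a secreted hepatic factor, had -0.48 ± 0.40 (adjusted p = 0.475). Ppara stood at 37.2 ± 9.93 FPKM in vehicle and 48.3 ± 5.28 FPKM in 326E livers (0.40 ± 0.24, adjusted p = 0.326). For mitochondrial fatty acid oxidation, of 22 tested, 12 rose, 0 fell and 10 did not pass (18 and 0 adjusted over the list alone). Their median was 0.70, with adjusted p = 7.31e-13 and adjusted p = 0.185 with an estimated correlation. Eci1 and Etfdh, enzymes of this pathway, rose by 1.17 ± 0.12 and 1.11 ± 0.10. For peroxisomal oxidation and biogenesis, of 29 tested, 13 rose, 0 fell and 16 did not pass (22 and 1 adjusted over the list alone). Their median was 0.52, with adjusted p = 7.03e-12 and adjusted p = 0.185 with an estimated correlation. Ehhadh and Acaa1b, a peroxisomal thiolase, rose by 3.66 ± 0.35 and 2.13 ± 0.28. The list medians of these 3 groups lay higher in each 326E library than in each vehicle library.

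Lipid synthesis genes rose as well: of 28 tested, 14 rose, 1 fell and 13 did not pass (17 and 3 adjusted over the list alone). Their median was 0.66, with adjusted p = 1.89e-06 and adjusted p = 0.144 with an estimated correlation. Scd1 rose by 6.44 ± 0.32 (adjusted p = 3.63e-05), Srebf1, the transcription factor of lipogenesis, by 1.42 ± 0.26 and Fasn, fatty acid synthase, by 1.34 ± 0.16. Acly stood at 20.8 ± 4.36 FPKM in vehicle and 22.3 ± 0.717 FPKM in 326E livers (0.12 ± 0.14, adjusted p = 0.619), and at -0.006 without vehicle replicate 2. For cholesterol synthesis and uptake, of 25 tested, 6 rose, 0 fell and 19 did not pass (6 and 0 adjusted over the list alone). Their median was 0.49, with adjusted p = 6.45e-06 and adjusted p = 0.436 with an estimated correlation. This median was 0.25 without vehicle replicate 2 (adjusted p = 0.0172) and 0.87 with only that replicate kept. Against chow the vehicle libraries stood at -0.07, -0.70 and 0.08 and the 326E libraries at 0.42, 0.10 and 0.14. Tm7sf2 and Nsdhl, enzymes of sterol synthesis, rose by 1.36 ± 0.09 and 1.24 ± 0.19. Bile acid genes did not pass as a list (median 0.14, 5 up and 0 down of 23, adjusted p = 0.0883 and adjusted p = 0.526 with an estimated correlation), but passed without vehicle replicate 3 (0.19, adjusted p = 0.0273), without 326E replicate 1 (0.24, adjusted p = 0.0364), without 326E replicate 2 (0.14, adjusted p = 0.0431), with no filter (0.12, adjusted p = 0.0309) and with only vehicle replicate 2 kept (0.36, adjusted p = 0.0129). Cyp7b1 rose by 1.94 ± 0.34, and did not pass with only vehicle replicate 2 kept (1.43, adjusted p = 0.165). Lipid droplet and VLDL genes (median 0.14, 2 up and 2 down of 20, adjusted p = 0.149 and adjusted p = 0.402 with an estimated correlation) passed only with no filter (0.14, adjusted p = 0.0316), of the settings run. Methyl donor genes (median 0.07, 3 up and 1 down of 26, adjusted p = 0.199 and adjusted p = 0.644 with an estimated correlation) passed only with vehicle replicate 2 alone (0.17, adjusted p = 0.0129), of the settings run. For oxidative phosphorylation, of 32 tested, 0 rose, 0 fell and 32 did not pass (0 and 0 adjusted over the list alone). Their median was 0.23, with adjusted p = 6.96e-05 and adjusted p = 0.436 with an estimated correlation, while 0 subunits passed singly by limma, 7 at an unadjusted p under 0.05.

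Macrophage and chemokine genes fell. For recruited and lipid-associated macrophages, of 29 tested, 0 rose, 14 fell and 15 did not pass (0 and 26 adjusted over the list alone). Their median was -0.66, with adjusted p = 7.31e-13 and adjusted p = 0.201 with an estimated correlation. Gpnmb and Trem2 fell, with log2 fold changes of -1.84 ± 0.34 and -1.58 ± 0.28, and did not pass with only vehicle replicate 2 kept (-1.99 and -1.69, adjusted p = 0.0992 and 0.0898). For chemokines, cytokines and inflammasome genes, of 27 tested, 0 rose, 10 fell and 17 did not pass (0 and 18 adjusted over the list alone). Their median was -0.66, with adjusted p = 3.76e-08 and adjusted p = 0.144 with an estimated correlation. Tnfaip3, which restrains NF-κB, fell by 2.14 ± 0.43 and did not pass without vehicle replicate 3 (-1.85, adjusted p = 0.0532), 326E replicate 2 (-2.15, adjusted p = 0.0559) or 326E replicate 3 (-2.10, adjusted p = 0.056). Ccl2 had -1.36 ± 0.41 (adjusted p = 0.0664) and passed without vehicle replicate 2 (-1.91, adjusted p = 0.00215). Vehicle replicates 1 and 3 carried the highest medians of this list, 1.67 and 1.83 against 1.43 in replicate 2. Neutrophil (median -0.64, 0 up and 1 down of 8, adjusted p = 0.0192 and adjusted p = 0.461 with an estimated correlation), dendritic cell (median -0.24, 0 up and 1 down of 14, adjusted p = 0.0267 and adjusted p = 0.459 with an estimated correlation) and interferon genes (median -0.29, 1 up and 2 down of 25, adjusted p = 0.0267 and adjusted p = 0.529 with an estimated correlation) passed with all libraries. The neutrophil call was lost without vehicle replicate 1, 2 or 3 (-0.81, -1.03 and -0.64, adjusted p = 0.0813, 0.0669 and 0.121) and with only replicate 2 kept (adjusted p = 0.287), and the dendritic cell and interferon calls without vehicle replicate 2 (adjusted p = 0.158 and 0.261) or 326E replicate 3 (adjusted p = 0.171 and 0.155). The dendritic cell median was -0.42 without vehicle replicate 1, -0.41 without 326E replicate 2 and -0.17 without vehicle replicate 2, and the interferon median -0.47 without vehicle replicate 3 and -0.15 without vehicle replicate 2. Kupffer cell markers (median 0.19, 1 up and 0 down of 15, adjusted p = 0.0893 and adjusted p = 0.521 with an estimated correlation) did not pass, except without vehicle replicate 1 (0.21, adjusted p = 0.0419), 326E replicate 1 (0.31, adjusted p = 0.0364) or 326E replicate 2 (0.31, adjusted p = 0.0425), with no filter (0.19, adjusted p = 0.0427), and with only vehicle replicate 2 kept (0.22, adjusted p = 0.0129). T and NK cell (median 0.08, 0 up and 0 down of 9, adjusted p = 0.369 and adjusted p = 0.717 with an estimated correlation) and B and plasma cell genes (median 0.06, 0 up and 0 down of 9, adjusted p = 0.778 and adjusted p = 0.805 with an estimated correlation) did not pass, with 1 and 0 genes at an unadjusted limma p under 0.05, the T and NK cell list passing without 326E replicate 3 (0.39, adjusted p = 0.0206).

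Matrix genes fell in part. For collagens and matrix proteins, of 29 tested, 0 rose, 11 fell and 18 did not pass (0 and 14 adjusted over the list alone). Their median was -0.47, with adjusted p = 3.84e-07 and adjusted p = 0.392 with an estimated correlation. Against chow, vehicle replicate 1 stood at 1.07, close to the 326E libraries (1.02 to 1.06), and vehicle replicates 2 and 3 at 1.67 and 1.49. With only vehicle replicate 2 kept the median was -0.84. Lum fell by 1.24 ± 0.23. Col1a1 fell from 33.4 ± 10.7 to 15.2 ± 2.43 FPKM (-1.05 ± 0.26, adjusted p = 0.0345), and did not pass without vehicle replicate 2 or 3 (-0.83 and -1.04, adjusted p = 0.0819 and 0.0878) or without 326E replicate 1, 2 or 3 (-1.17, -0.96 and -1.03, adjusted p = 0.0558, 0.113 and 0.098). For matrix remodelling, of 26 tested, 0 rose, 10 fell and 16 did not pass (0 and 13 adjusted over the list alone). Their median was -0.58, with adjusted p = 4.52e-08 and adjusted p = 0.185 with an estimated correlation. Mmp12 fell by 1.54 ± 0.20. The stellate cell list (median -0.23, 0 up and 2 down of 24, adjusted p = 0.0471 and adjusted p = 0.594 with an estimated correlation) passed with all libraries, and its call was lost without vehicle replicate 2 or 3 (-0.13 and -0.13, adjusted p = 0.321 and 0.239), without 326E replicate 3 (-0.15, adjusted p = 0.261) or without chow replicate 2 (adjusted p = 0.0523), and under several other settings, while its median was -0.41 without vehicle replicate 1. Ctgf, a matricellular factor of this list, fell by 1.66 ± 0.26. Acta2 had 0.25 ± 0.58 (adjusted p = 0.816) and turned to -0.28 without vehicle replicate 1. Cholangiocyte genes (median -0.46, 1 up and 0 down of 16, adjusted p = 0.0947 and adjusted p = 0.529 with an estimated correlation) did not pass, except without vehicle replicate 1 (-0.65, adjusted p = 0.0075) or 326E replicate 1 (-0.73, adjusted p = 0.0247), with no filter (-0.40, adjusted p = 0.0291), with array weights (-0.60, adjusted p = 0.0438), and with only vehicle replicate 2 kept (-0.59, adjusted p = 0.0206). Krt23, a keratin of that list, rose by 3.23 ± 0.47. Endothelial markers (median 0.13, 0 up and 0 down of 19, adjusted p = 0.274 and adjusted p = 0.644 with an estimated correlation) did not pass, with 5 genes at an unadjusted limma p under 0.05. For cell cycle genes, of 27 tested, 0 rose, 6 fell and 21 did not pass (0 and 7 adjusted over the list alone). Their median was -0.21, with adjusted p = 0.000588 and adjusted p = 0.185 with an estimated correlation. Cdkn1a fell by 1.75 ± 0.26. The values of Ctgf (-1.71, adjusted p = 0.0821), Col1a1 (-1.50, 0.0577), Krt23 (2.84, 0.0898) and Cdkn1a (-1.51, 0.0828) did not pass with only vehicle replicate 2 kept.

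Among protein-coding genes whose groups did not overlap, those with the largest falls under 326E were Egr1 (-3.76 ± 0.93), Btg2 (-3.74 ± 0.84), Atf3 (-3.20 ± 0.59), Thbs1 (-3.16 ± 0.71) and Ier3 (-2.98 ± 0.73), and these moved with vehicle replicates 1 and 3. Btg2, which slows cell division, stood at 295.2, 21.5 and 307 FPKM in vehicle replicates 1, 2 and 3 and at 7.53 to 9.8 FPKM under 326E. Egr1, a transcription factor of the early response, stood at 107, 9.3 and 145 FPKM in vehicle and at 2.74 to 3.38 FPKM under 326E. Without vehicle replicate 3, the values did not pass for Egr1 (adjusted p = 0.0989), Btg2 (0.0721), Thbs1 (0.0719) and Ier3 (0.0903). The same held without vehicle replicate 1 (0.0976, 0.0667, 0.0703 and 0.0943), 326E replicate 1 (0.0791, 0.0583, 0.0586 and 0.0842), 326E replicate 2 (0.0971, 0.0763, 0.0767 and 0.0902) and 326E replicate 3 (0.0917, 0.071, 0.0728 and 0.0857). Over these the log2 fold changes were -3.818 to -3.048 for Egr1, -3.832 to -3.101 for Btg2, -3.245 to -2.588 for Thbs1 and -3.034 to -2.345 for Ier3, the smallest of each without vehicle replicate 3. With only vehicle replicate 2 kept, Egr1 stood at -1.35 (adjusted p = 0.398), Ier3 at -0.81 (0.0501), Thbs1 at -1.08 (0.0847) and Atf3 at -1.57 (0.0501), and Btg2 still passed at -1.24 (0.0334).

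For the NRF2 list, of 22 tested, 1 rose, 6 fell and 15 did not pass (2 and 8 adjusted over the list alone). Their median was -0.35, with adjusted p = 0.00275 and adjusted p = 0.192 with an estimated correlation. Against chow its median was 0.45, -0.04 and 0.44 in vehicle replicates 1, 2 and 3 and -0.16 to -0.10 in the 326E libraries, and with only vehicle replicate 2 kept the list passed (-0.32, adjusted p = 0.0411). Cbr3, a carbonyl reductase, fell by 1.16 ± 0.20. The unfolded protein list (median -0.38, 0 up and 2 down of 24, adjusted p = 0.0192 and adjusted p = 0.299 with an estimated correlation) passed, a call lost without 326E replicate 3 (-0.44, adjusted p = 0.0632). Its 2 fallen members were Herpud1 and Atf3, the latter an early gene. Glycolysis and gluconeogenesis (median -0.17, 0 up and 6 down of 26, adjusted p = 0.0117 and adjusted p = 0.345 with an estimated correlation) passed, a call lost with only vehicle replicate 2 kept (-0.15, adjusted p = 0.0771), and its median was -0.275 without 326E replicate 3. Hk3, a hexokinase of myeloid cells, fell by 1.05 ± 0.12. Hepatocyte genes (median 0.14, 1 up and 2 down of 30, adjusted p = 0.369 and adjusted p = 0.796 with an estimated correlation), whose median turned to -0.03 with quantile normalization, and acute phase genes (median -0.16, 0 up and 1 down of 29, adjusted p = 0.286 and adjusted p = 0.805 with an estimated correlation) did not pass, except the latter with quantile normalization (-0.30, adjusted p = 0.0197). Asl, of the urea cycle, fell by 1.05 ± 0.18. Neither Asl (-1.105, adjusted p = 0.0849) nor Cbr3 (-1.40, 0.0566) passed with only vehicle replicate 2 kept. Xenobiotic metabolism (median 0.12, 1 up and 3 down of 21, adjusted p = 0.774 and adjusted p = 0.881 with an estimated correlation) did not pass, with a mean of -0.13 against its positive median. The circadian clock (median -0.13, 1 up and 5 down of 16, adjusted p = 0.14 and adjusted p = 0.461 with an estimated correlation) did not pass, and Nr1d1, a clock repressor, rose by 1.29 ± 0.13. Carry-over markers (median 0.97, 1 up and 0 down of 13, adjusted p = 0.0471 and adjusted p = 0.319 with an estimated correlation) passed, and the call was lost without vehicle replicate 1 or 3 (adjusted p = 0.094 and 0.0849), without 326E replicate 1 or 2 (adjusted p = 0.0602 and 0.0754) and with only vehicle replicate 2 kept (adjusted p = 0.261), and under several other settings.

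**Figure D3:**
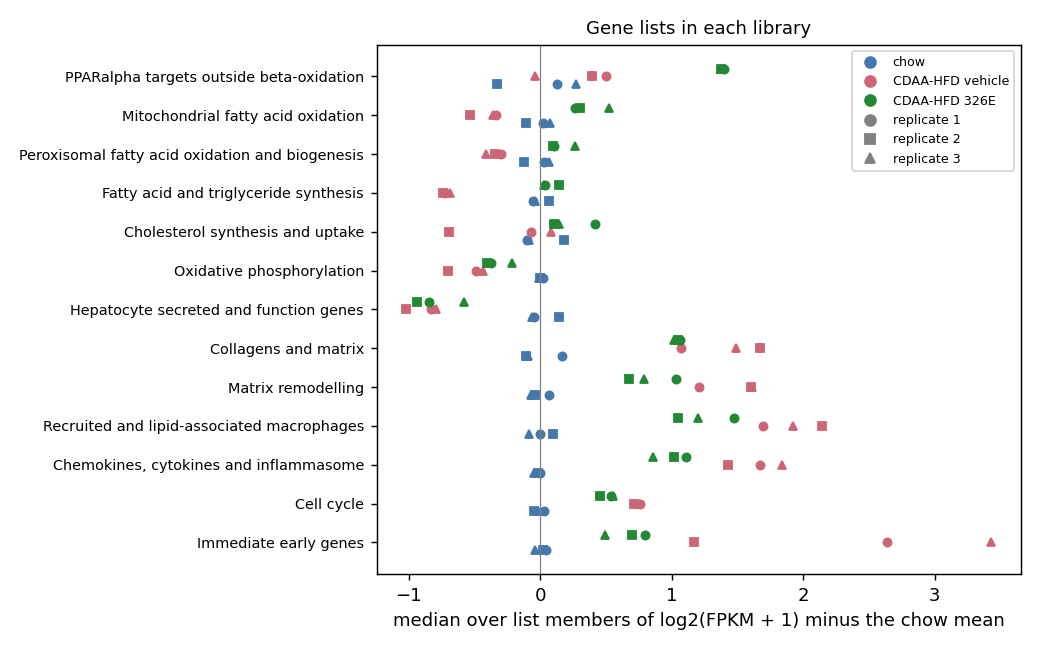
Median over the members of 13 gene lists of log2(FPKM+1) minus the chow mean, for each library, coloured by group with a symbol for each replicate. The lists of PPARα targets, fatty acid oxidation and lipid synthesis lie higher in every 326E library than in every vehicle library, and immediate early genes lie at 1.17 in vehicle replicate 2 against 2.64 and 3.43 in replicates 1 and 3.

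Genes changed by the diet were then set against genes changed by 326E. Of the 1574 genes called for 326E, 80.7% were also called for the diet, and 95.1% of those went the opposite way: 770 rose with the diet and fell under 326E, and 438 fell and then rose. Another 62 went the same way in both comparisons, 40 up and 22 down. This count was 41 without chow replicate 1, 36, 36 and 34 without vehicle replicates 1, 2 and 3, 39 and 22 without 326E replicates 1 and 2, and 10 with only vehicle replicate 2 kept. Independent overlap would give 185.9 and 141.9 opposite genes, values which do not allow for the shared vehicle libraries. In 100 simulations without an effect of 326E, with these libraries shared and genes varying independently, at most 1 gene was called for 326E, so that the opposite calls there show nothing. The 1574 genes with the smallest p for 326E were therefore taken in each simulation: at most 600 went the opposite way to a diet call, and of those that were diet calls at most 69.5% did, 64.9% on average. The 1208 opposite genes are 21.1% of the diet calls. Their number was 662 without vehicle replicate 3, 769, 509 and 531 without 326E replicates 1, 2 and 3, and 250 with only vehicle replicate 2 kept. Among diet calls, 86.9% had the opposite sign under 326E, called or not, against 56.6% of diet calls on average and at most 58.4% in the simulations. Because the simulated genes varied independently, the highest simulated values are not bounds for genes that move together. The covariance of the fold changes across genes was -0.22 (r = -0.65). The mean r was -0.50 in simulations without any effects, and -0.13 in those with the diet effect kept and no effect of 326E. The vehicle libraries shared by both comparisons alone gave a covariance of -0.02 in simulations without effects. With vehicle libraries split between the comparisons the covariance was -0.19 (r = -0.52). Genes are not independent replicates.

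**Figure D4:**
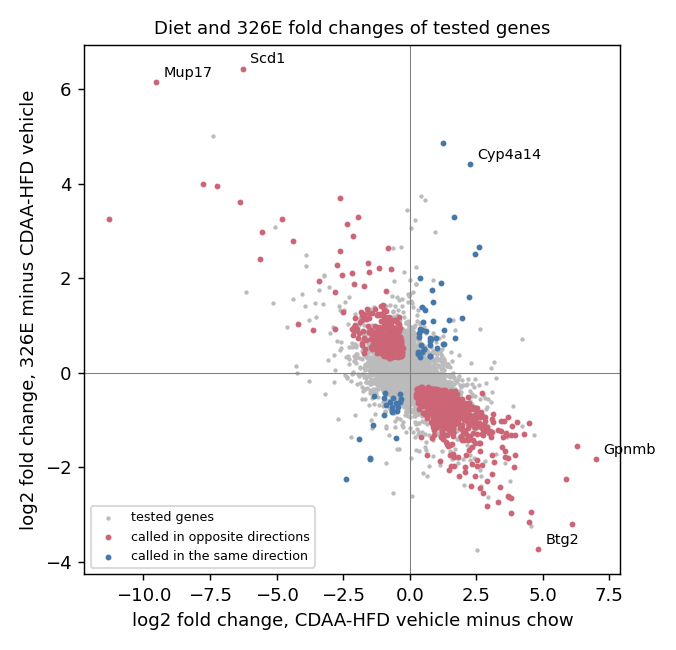
Log2 fold change of the diet against that of 326E for the tested genes, on the log2(FPKM+1) scale, with genes called in both comparisons coloured by whether the directions are opposite (1208) or the same (62). Both axes use the same vehicle libraries, which gives a covariance of -0.02 without any effect.

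Scd1, Mup17 and Hsd3b5 fell with the diet, at -6.26 ± 0.32, -9.53 ± 0.47 and -6.37 ± 0.62, and rose under 326E by 6.44 ± 0.32, 6.16 ± 0.47 and 3.61 ± 0.62, the last not passing with only vehicle replicate 2 kept (2.002, adjusted p = 0.0843). The Mup genes, which encode urinary proteins, and Hsd3b5, a steroid dehydrogenase, have close paralogs, so their single values are uncertain. Gpnmb, Mmp12 and Trem2 rose with the diet and fell under 326E, but were not the largest such changes. Atf3, Btg2, Ier3 and Igfbp1 also rose with the diet, and they fell further under 326E. For all of these, vehicle replicate 2 was the lowest of the vehicle libraries, though for Igfbp1 by little (586.7, 548.3 and 785.3 FPKM in vehicle replicates 1, 2 and 3). Some genes did not follow this pattern, and apart from Cyp4a14, which was fixed beforehand, they were chosen after their values were seen. Cyp4a14 and Acot2, a mitochondrial thioesterase, rose in both comparisons, Acot2 by 2.47 ± 0.26 and then 2.51 ± 0.26, and Cyp4a14 did not pass for the diet with only vehicle replicate 2 kept (2.21, adjusted p = 0.0984). Rgs16, a regulator of G protein signalling, and Slc22a7, an organic anion transporter, fell in both, Slc22a7 at -1.90 ± 0.15 and then -1.41 ± 0.15. Another 304 genes were called for 326E and not for the diet, 203 of them higher. They include Mogat1, which makes diacylglycerol (3.44 ± 0.15), and Slco1a4, an organic anion transporter (-2.60 ± 0.28). Whether the diet effect on such genes is absent was not tested, and values without single libraries were not computed for Acot2, Rgs16, Slc22a7, Mogat1 and Slco1a4.

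The third comparison asked how far livers of 326E-treated mice stayed from chow, 326E against chow. As lists, PPARα targets, macrophage and collagen genes stood above chow, and hepatocyte genes below it. None of these lists passed with an estimated correlation (adjusted p = 0.144 to 0.255), and quantile normalization ended the hepatocyte call. Cyp4a14 was at 33.9 ± 23.7 FPKM in chow and 2858 ± 545 FPKM in 326E livers. Trem2 was at 0.24 ± 0.119 and 3.93 ± 2.35 FPKM, and Scd1 at 1623 ± 634 and 1779.7 ± 393 FPKM (0.18 ± 0.32, adjusted p = 0.725). In all, 3688 genes passed, 1974 higher and 1714 lower, with 502 and 357 changed at least 2-fold on the log2(FPKM+1) scale. Of the called genes 53.5% were higher, and 87% when scaled to total assigned reads, which moved the median of all genes from -0.02 to 0.24. The count was 2393 without 326E replicate 2. Of the 5721 diet calls, 3023 were also called here, 2992 in the same direction and 31 in the other, and 2698 were not. Another 665 genes called here were not called for the diet.

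Among the lists, PPARα targets rose against chow (median 1.35, 21 up and 0 down of 32, adjusted p = 4.96e-15 and adjusted p = 0.144 with an estimated correlation), as did mitochondrial oxidation (median 0.33, 10 up and 2 down of 22, adjusted p = 0.00681 and adjusted p = 0.469 with an estimated correlation) and lipid droplet and VLDL genes (median 0.51, 9 up and 1 down of 20, adjusted p = 0.00491 and adjusted p = 0.144 with an estimated correlation). Peroxisomal oxidation and biogenesis (median 0.14, 9 up and 5 down of 29, adjusted p = 0.235 and adjusted p = 0.766 with an estimated correlation) did not pass, except with quantile normalization (0.17, adjusted p = 0.00316), of the scalings run. Macrophage (28 up and 0 down of 29, adjusted p = 2.04e-17 and adjusted p = 0.144 with an estimated correlation), chemokine (median 1.01, 19 up and 0 down of 27, adjusted p = 2.01e-10 and adjusted p = 0.103 with an estimated correlation) and dendritic cell genes (median 0.95, 12 up and 0 down of 14, adjusted p = 4.43e-08 and adjusted p = 0.144 with an estimated correlation) were higher. Collagens (median 1.04, 23 up and 1 down of 29, adjusted p = 1.91e-11 and adjusted p = 0.255 with an estimated correlation), matrix remodelling (median 0.84, 18 up and 1 down of 26, adjusted p = 7.79e-09 and adjusted p = 0.144 with an estimated correlation), stellate cell (median 0.76, 12 up and 0 down of 24, adjusted p = 4.34e-07 and adjusted p = 0.295 with an estimated correlation) and cell cycle genes (median 0.49, 17 up and 0 down of 27, adjusted p = 5.63e-09 and adjusted p = 0.103 with an estimated correlation) were also higher. Hepatocyte (median -0.70, 1 up and 17 down of 30, adjusted p = 3.37e-08 and adjusted p = 0.251 with an estimated correlation), bile acid (median -0.93, 2 up and 14 down of 23, adjusted p = 9.16e-05 and adjusted p = 0.251 with an estimated correlation), acute phase (median -1.01, 0 up and 13 down of 29, adjusted p = 1.54e-05 and adjusted p = 0.393 with an estimated correlation) and oxidative phosphorylation genes (median -0.32, 0 up and 11 down of 32, adjusted p = 9.84e-06 and adjusted p = 0.319 with an estimated correlation) were lower, the median of the last turning to 0.03 when scaled to total assigned reads. Quantile normalization ended the calls of hepatocyte (-0.14, adjusted p = 0.15) and oxidative phosphorylation genes (-0.08, adjusted p = 0.395). Fatty acid synthesis (median 0.11, 7 up and 6 down of 28, adjusted p = 0.774 and adjusted p = 0.827 with an estimated correlation) did not pass, with a mean of -0.06, and Acly stayed below chow at -0.94 ± 0.14 (adjusted p = 0.00142). Cholesterol synthesis (median 0.22, 1 up and 1 down of 25, adjusted p = 0.216 and adjusted p = 0.767 with an estimated correlation) did not pass, except with quantile normalization (0.33, adjusted p = 0.0149), of the scalings run. Camera at its preset correlation also called interferon (median 0.45, adjusted p = 0.000236), T and NK cell (0.66, 0.00641), endothelial (0.31, 0.00491) and cholangiocyte genes (0.60, 0.00522) higher. Methyl donor (-0.33, 0.00878), xenobiotic (-0.41, 0.00643) and carry-over genes (-0.92, 0.0429) were called lower. The T and NK cell, endothelial and xenobiotic lists had not passed for the diet or 326E with all libraries. For this comparison the lists were not tested without single libraries. Camera with its preset correlation called 21 of the 31 lists here, and 19 in each of the other comparisons. With an estimated correlation it called 0 in each comparison, with 6, 8 and 7 lists at an unadjusted p under 0.05 for the diet, 326E and 326E against chow, and fry called 22 here, 26 for the diet and 12 for 326E.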

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

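Values scaled to total assigned reads, with a GC trend removed, with the Mup family left out and with only vehicle replicate 2 kept were chosen after the data were seen, and the other alternatives before. With each library left out in turn, the diet gave 4662 to 5667 genes, 326E 647 to 1635, 326E against chow 2393 to 3711, opposite calls 509 to 1187, the covariance -0.26 to -0.20, and lists called 18 to 22 for the diet and 15 to 21 for 326E. Without a filter 326E gave 1030 genes and 770 opposite calls, where more genes were tested. The labels do not say that the numbers of the libraries pair the samples. Correlations of same-number libraries lay between -0.24 and 0.02, and those of different numbers between -0.18 and 0.19. This gave no sign of pairing but cannot exclude it with so few libraries. A replicate block as if for pairing gave 1037 genes for 326E and 775 opposite calls. A change of at least 2-fold left 1547, 332 and 859 genes for the diet, 326E and 326E against chow, a stricter call by construction. With only vehicle replicate 2 kept there were 3456 diet genes, 321 for 326E and 250 opposite calls, with fewer samples. The covariance was -0.44 with a pseudocount of 0.1, -0.10 with 5, -0.12 without a filter and -0.50 with voom, which change the scale or the genes entered. With an estimated correlation 0 lists were called for the diet and 0 for 326E, against 19 and 19.

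Of 59 named genes called for 326E, 30 were called without each library in turn and 16 under every setting that gave a value; for the diet these were 72 and 62 of 76. Of 19 lists called in each comparison, 18 for the diet and 13 for 326E were called without each library in turn, and 11 and 12 under every setting run, the estimated correlation apart. Of the 19 called for 326E, 4 lost the call with array weights and 3 with a mean FPKM of at least 1. The passages on single lists do not name every such loss. Directions turned for Sqle in the diet comparison without chow replicate 1 (-0.02, with 0.42 the highest without a library) and with only vehicle replicate 2 kept (-0.34), Acly under 326E without vehicle replicate 2 (-0.006, highest 0.27), Acta2 under 326E without vehicle replicate 1 (-0.28, highest 0.67), and Sqle (0.36) under 326E with only vehicle replicate 2 kept; none of these values passed, and the cause was not tested. The planned median-of-ratios scaling moved almost nothing, because the deposited values carry it already. Array weights, quantile normalization and the other alternatives kept each count within 1.5 times. Of the 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05, 1 gave as many genes in each comparison, the real one: 5721 for the diet against at most 0 in other splits, 1574 for 326E against at most 1, and 3688 for 326E against chow against at most 1.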

Other observations

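All of the tests of explanations in this part, and the lists they use beyond the fixed ones, were chosen after the results were seen, and the criterion of the 2 tests of hepatocyte share was changed more than once after their values were known. Of 19 tested male-biased liver genes outside the Mup family, 19 fell with the diet, with a median of -2.29, and under 326E 9 rose and 0 fell, with a median of 1.04. This list was written after the values were seen, was not tested against other genes, and shares Cyp7b1, Slco1a1, Nudt7 and other members with the fixed lists, so its counts describe these genes only. Of the 9 that rose under 326E, Cyp4a12a and Cyp4a12b are also in the list of PPARα targets, which rose. Elovl3, a fatty acid elongase, fell from 171 ± 35 FPKM in chow to 5.26 ± 1.72 FPKM in vehicle livers and rose to 58.9 ± 17.9 FPKM under 326E. Of 19 tested Mup genes 17 fell with the diet and 10 rose under 326E, with paralogs that make single values uncertain. Against chow, 14 of the 19 genes outside the Mup family were still lower under 326E. Igfbp1, a secreted binding protein for insulin-like growth factors, rose with the diet by 3.71 ± 0.40 and fell under 326E, at -2.64 ± 0.40.

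Clock genes moved in part: Per1, Per2 and Cry1 rose with the diet and fell under 326E, and Nr1d1 fell and then rose, at -1.81 ± 0.13 and 1.29 ± 0.13. Cry1 stood at 0.86 ± 0.15 and -1.15 ± 0.15. The Per1 call for 326E was lost, at log2 fold changes of -1.442 to -1.236 against -1.422, without vehicle replicate 1 (adjusted p = 0.0797) or 3 (0.106) and without 326E replicate 1 (0.0811), 2 (0.104) or 3 (0.0904). The labels give no hour of collection. Xist was at no more than 0.01 FPKM and Ddx3y at 14.1 to 22.6 FPKM in the 9 libraries.

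Immediate early genes were higher in vehicle livers, 28 of 32 tested having risen with the diet, and 16 fell under 326E. Whether the early gene response of vehicle replicates 1 and 3, which stood apart, gave the list calls of 326E cannot be told: with vehicle replicate 2 alone 16 of 19 lists stayed called in their direction at the preset correlation, which goes against it, but this rests on 1 vehicle library and no list is called with all libraries at an estimated correlation. Handling or delay when the livers of those replicates were collected may account for the early genes themselves and cannot be told apart from an effect of the diet: replicate 2 lay above the highest 326E library by only 0.37, and the spread within vehicle was wider than within 326E. An effect of 326E on early genes stays open and untested beyond this.

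For the male-biased genes, reads shared among Mup paralogs bear on the Mup genes only. The fall outside that family, with an upper quartile of -1.94 for the diet, does not test such sharing. Whether it distorts the Mup values stays open. A lower share of hepatocytes as the whole cause cannot be decided with this list. The median of the male-biased genes lay below the lower quartile of the fixed hepatocyte list, at a difference of -1.07. Their upper quartile did too, at -0.72. The male-biased list was written after its falls were seen, so such a gap could come from the choice of genes. A shift in the sex-biased programme set by growth hormone may be a hypothesis for follow-up, and cannot be told apart from other causes. Of 19 listed female-biased genes 10 were tested. With the diet 6 rose and 2 fell, and under 326E 2 rose, among them Acot3 of the PPARα list, and 3 fell. Their median against chow was 1.41, 0.56 and 2 in vehicle replicates 1, 2 and 3, lowest in replicate 2 as for the early genes. No hormone was measured.

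For the lipogenic genes that rose under 326E, a higher share of hepatocytes as the whole cause cannot be decided. The criterion was changed after the values were known, and the outcome depends on it. Such a share would raise the hepatocyte list by about the lipogenic median of 0.66. That median lay above the upper quartile of the hepatocyte list by 0.38. The hepatocyte list had a median of 0.14 and quartiles of -0.14 and 0.28. The lipogenic quartiles were 0 and 0.85, so the ranges overlap. With the stricter criterion of separated quartile ranges the difference was -0.28, which leaves this open. A more recent meal when the livers were collected could raise such genes and stays open: fasting-induced genes had a median of -0.51 under 326E, with 2 of 16 lower and 0 higher. The feeding state is not in the labels, and an effect of 326E itself stays among the explanations.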
